A study of Mus musculus with 4 samples.

How the data were processed

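CD8 T cells from skeletal muscle were sorted as Nur77-GFP+ or as TSKb20 tetramer+, each from 5 mice and then pooled, and were made into 10x 5' expression libraries and V(D)J-enriched TCR libraries, per the labels' protocols. The 4 samples form 4 groups of 1 library each. Per the submitters' processing notes and the file headers, Cell Ranger 6.1.2 and the build mm10/GRCm38 were used by the authors. The V(D)J reference, the cell filters and the way in which the expression libraries were joined are not given in the sources used here.

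The deposited expression matrix holds raw UMI counts for 32285 genes and 6375 barcodes, per the file headers. Of these barcodes, 3285 end in 1 and 3090 in 2, and no label ties an ending to a sorted population. The matrix was therefore used as 1 pooled sample, and the endings only as unassigned sets of cells. The deposited clonotype tables give the cell count of each clonotype and that count as a fraction of the table's cells, both made by the authors, with the CDR3 sequences and notes on iNKT and MAIT evidence. No column was left unmatched (0).

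Clonotype expansion was measured on the clonotypes as deposited. For sharing, clonotypes with the same set of CDR3 nucleotide sequences were merged, a step added after the tables had been seen, which concerned 63 clonotypes (248 cells) of the Nur77-GFP+ table and 24 (32 cells) of the TSKb20 table. A clonotype was shared when its whole set was identical in both tables. J segments were not assigned, as no genome was used here. Short motifs, 3 residues within the beta CDR3 or the last 7 residues of the alpha CDR3 and present in at least 10 sequences of a library, were compared after the data had been seen (137 beta and 33 alpha motifs).

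Cells with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept (6031 cells). Of the others, 239 had too few genes or UMIs and 105 failed on mitochondrial UMIs alone. Scrublet (scanpy 1.11.5), run per barcode ending, called 7 doublets, 0.116%, which is too few for the caller to have worked, so doublets were not effectively removed. In 2 alternatives added after seeing the data, the 5% of cells with the highest Scrublet scores, or cells with 2 Trbv genes of at least 2 UMIs each, were removed. The 6024 kept cells were clustered with Leiden (leidenalg 0.10.2, resolution 0.6) on 2000 variable genes without TCR, immunoglobulin, mitochondrial, ribosomal protein and sex genes, 30 components and 15 neighbours.

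The marker genes, the gene lists, the rules for named items and all alternatives not marked as added were fixed before the data were examined, but the rule that turns them into names was set after cluster profiles had been seen. A cluster was named when at least 3 markers were 2-fold above all other kept cells at 20 CPM or more, with at least 1 among its top 10 genes by fold, and more of the set than of any other. The CD8 T and CD4 T marker sets were not used for names. Cluster 7 met this rule for exhausted CD8 T cells but was left without a name after its leading genes had been seen. CD8 T cells were all kept cells outside clusters named as another lineage. This class, too, was settled after seeing the data: an earlier version also left out cluster 13 (29 cells) by a second rule, which removed larger numbers of cells under other settings and was dropped. Alternatives without cluster 13 or without cluster 7, both added after seeing the data, are included. Under 4 of the alternatives further clusters took the name of muscle or erythroid cells and so left the class. Cells left out, with B-like cells, numbered 97 in the main setting and 536 at resolution 1.0. They numbered 697 without cells of 2 Trbv genes, 831 at 20% mitochondrial UMIs and 477 with 200 genes. The class fell from 5927 cells to 5488, 4454, 5289 and 5676 in the same order.

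CPM values were summed counts of a set of cells divided by their total, with exact Poisson intervals. Of the members of the 11 gene lists, Mx1 alone had no value in the matrix. Some genes that the rules below name are not reported here. The genes named from each list are the up to 4 of highest CPM and the 2 of lowest CPM over CD8 T cells. For barcode endings, named genes are at least 50 CPM in 1 set, exclude TCR, immunoglobulin, mitochondrial, ribosomal protein and sex genes, and are the 12 of largest ratio in each direction whose interval excludes 1.5, plus 13 genes fixed beforehand. Genes named for a cluster are among its 5 of highest fold. Ratios have exact conditional binomial intervals. List medians were ranked among 10000 random lists matched on mean expression. TMM factors came from edgeR 4.0.16 in R 4.3.3. A V gene was assigned to a cell when it had at least 2 UMIs and more than 2 times those of the next. Named clonotypes are the 10 largest per library and the 10 shared ones of largest smaller share.

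On simulated counts for 2854 genes with Poisson noise alone, the ratio step for barcode endings recovered 68 of 68 genes changed 2-fold, 63 of 63 changed 3-fold and 69 of 69 changed 4-fold, and called 0 unchanged genes. That test holds no variation between animals. Cells of the 2 endings were thinned to 2000 UMIs in 1 random draw. The grouping step found a simulated group of 7 similar sequences. A simulated count of 28 of 28 shared clonotypes was made on clonotype numbers without the matching of sequences. It could not fail and does not test the sharing step. Other alternatives concerned the identity of a clonotype, the chains required, thinning, mitochondrial limits of 5% and 20%, at least 200 genes with no UMI minimum, resolutions of 0.3 and 1, the total used for CPM, means over cells, and the UMIs required for a V gene. numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and Python 3.11.15 were used.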

Results

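The series addressed which CD8 T cells respond in skeletal muscle when mice chronically infected with the protozoan parasite Trypanosoma cruzi meet the parasite again. Nur77-GFP reporter mice, in which green fluorescent protein follows the Nr4a1 (Nur77) gene that T cell receptor (TCR) signalling switches on, were in the chronic phase (day 336 of infection by the labels) and had been reinfected in muscle 13 days before their T cells were taken. CD8 T cells were sorted either as Nur77-GFP+ or as binding the TSKb20 tetramer, a peptide-MHC reagent that stains CD8 T cells specific for a trans-sialidase peptide of the parasite. Each kind came from 5 mice and was pooled. Each pool gave 1 single-cell expression library and 1 TCR library. The Nur77-GFP+ TCR table held 1127 clonotypes in 2408 cells, and the TSKb20 table held 282 clonotypes in 2267 cells. The expression values formed 1 matrix of 6375 barcodes and 38763010 unique molecular identifiers (UMIs), with a median of 5406 UMIs per barcode. Expression is given as CPM, the summed UMIs of a gene per 1e6 UMIs of the same cells. Since each sorted population was 1 pooled library, differences had no replicate check, no p-value was computed, and the 95% intervals below (exact Clopper-Pearson for shares, exact Poisson for counts) cover counting error only.

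The TSKb20 tetramer+ population was dominated by few clonotypes, whereas the Nur77-GFP+ population was spread over many. The 10 largest clonotypes held 62.3% of TSKb20 cells (60.3 to 64.3) and 28.0% of Nur77-GFP+ cells (26.2 to 29.9). The largest clonotype held 16.9% (15.3 to 18.5) of TSKb20 cells, 382 cells, and 8.35% (7.27 to 9.52) of Nur77-GFP+ cells, 201 cells. Clonotypes seen in 1 cell made up 40.3% (38.3 to 42.3) of Nur77-GFP+ cells and 8.03% (6.94 to 9.22) of TSKb20 cells. It took 64 clonotypes to reach 50% of the Nur77-GFP+ cells and 6 to reach 50% of the TSKb20 cells. The effective number of clonotypes, the exponential of the Shannon index, was 376.8 in the Nur77-GFP+ library and 41.1 in the TSKb20 library. The Nur77-GFP+ values depended on the chains required. With at least 1 alpha and 1 beta chain per clonotype, the clonotypes holding 50% of cells numbered 36 and 6, and the effective numbers were 242.8 and 34.4. With exactly 1 of each, they were 29 and 5, and 202.3 and 28.9. After the Nur77-GFP+ library was thinned to 2267 cells in 100 draws, the effective number of the deposited clonotypes lay between 354.9 and 376.1.

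**Figure D1:**
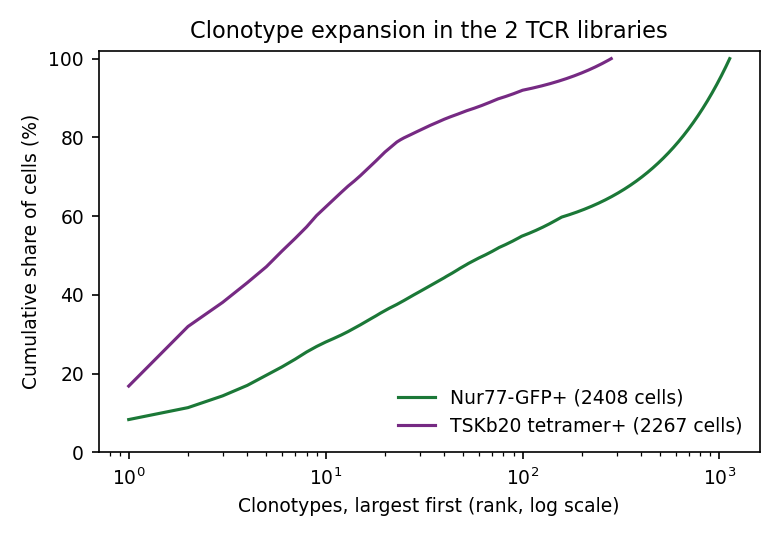
Cumulative share of cells (y axis, percent) against clonotype rank, largest first (x axis, log scale), for the Nur77-GFP+ library (green line, 2408 cells) and the TSKb20 tetramer+ library (purple line, 2267 cells). The TSKb20 line reaches 62.3% at rank 10, where the Nur77-GFP+ line is at 28.0%.

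The populations shared 54 clonotypes whose whole sets of CDR3 nucleotide sequences were identical, and these weighed far more in the Nur77-GFP+ library. Both chains were not required, so a set could hold an alpha or a beta chain alone. Shared clonotypes held 996 Nur77-GFP+ cells, or 41.4% (39.4 to 43.4), and 241 TSKb20 cells, or 10.6% (9.39 to 12). For this comparison, clonotypes listed more than once with the same sequences were merged, which left 1095 and 270. The most frequent shared clonotype, with beta CDR3 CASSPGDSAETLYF and alpha CDR3 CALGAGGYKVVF, was the largest of the Nur77-GFP+ library (201 cells) and ranked 9 in the TSKb20 library (66 cells, 2.91%, 2.26 to 3.69). The clonotype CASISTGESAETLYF with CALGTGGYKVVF had 44 Nur77-GFP+ cells and 26 TSKb20 cells. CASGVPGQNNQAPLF with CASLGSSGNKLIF had 93 and 10 cells, and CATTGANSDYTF with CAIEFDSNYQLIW had 84 and 7 cells. After this merging, all 10 of the largest Nur77-GFP+ clonotypes occurred in the TSKb20 library, with 136 cells in total. Of the 10 largest TSKb20 clonotypes, 1 occurred in the Nur77-GFP+ library. The other 9, with 1347 TSKb20 cells, had 0 of 2408 Nur77-GFP+ cells, which by the limit of 3 counts allows a share of up to 0.125% each (exact upper bound 0.153%). Counting only clonotypes with at least 2 cells in each library, 30 were shared, and counting any beta CDR3 amino-acid sequence in common, 96 Nur77-GFP+ clonotypes were.

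**Figure D2:**
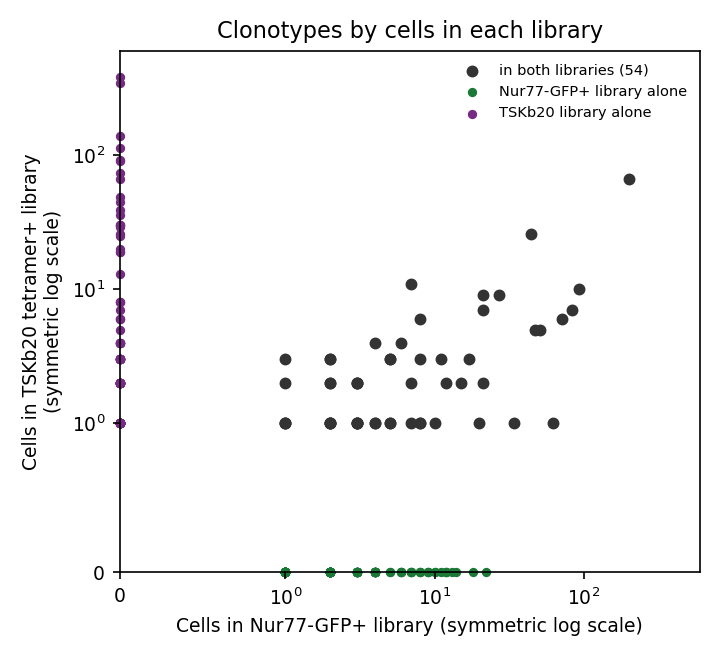
Cells per clonotype in the Nur77-GFP+ library (x axis) and the TSKb20 tetramer+ library (y axis), both on symmetric log scales, with 1 point per clonotype after merging identical sequences. The 54 shared clonotypes are dark points, and the clonotypes of 1 library alone lie on the axes, among them the TSKb20 clonotypes of 382 and 343 cells.

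The TSKb20 beta chains more often had CDR3 of 15 residues and more often fell into groups of similar sequences. Mean lengths were close, at 14.05 residues in TSKb20 and 13.87 in Nur77-GFP+. A length of 15 residues was found in 33.2% (27.4 to 39.4) of 250 TSKb20 beta nucleotide sequences and in 20% (17.6 to 22.5) of 1055 Nur77-GFP+ ones. Weighted by cells, these shares were 66.2% and 20.2%. Groups of at least 3 beta CDR3 of equal length, linked by single residue differences, took in 17.2% (12.6 to 22.5) of 239 TSKb20 amino-acid sequences. They took in 8.59% (6.95 to 10.5) of 1024 Nur77-GFP+ sequences, and between 0% and 6.28% when 239 of these were drawn 100 times. The largest TSKb20 group had 16 members of 15 residues and 650 cells, led by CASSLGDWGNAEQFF. An alpha and a beta chain were both found for 96.0% (95.1 to 96.8) of TSKb20 cells and 85.3% (83.8 to 86.7) of Nur77-GFP+ cells. Of the TSKb20 clonotypes ranked 1 to 4, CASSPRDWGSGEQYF with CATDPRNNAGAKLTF had 382 cells and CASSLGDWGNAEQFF with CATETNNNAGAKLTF had 343 cells. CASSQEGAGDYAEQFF with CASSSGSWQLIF had 139 cells, and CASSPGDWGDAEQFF with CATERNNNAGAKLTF had 113 cells.

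**Figure D3:**
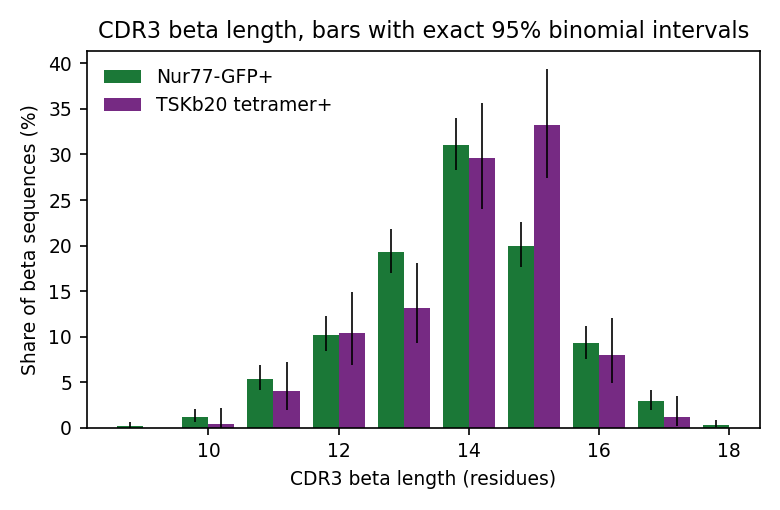
Share of beta nucleotide sequences (y axis, percent) by CDR3 length in residues (x axis) in the Nur77-GFP+ library (green) and the TSKb20 tetramer+ library (purple), with exact 95% binomial intervals. At 15 residues the bars stand at 20% and 33.2%.

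The expression matrix described both sorted populations together, because its barcodes carry endings that match no label. After filtering, 6024 cells remained in 13 clusters, numbered by size. Clusters with naive or memory CD8 markers (clusters 3 and 5) held 899 cells, 14.9% (14.0 to 15.9). An effector-like cluster 2 held 13.9% (13.1 to 14.8) of the kept cells and a cycling-like cluster 8 held 3.44% (2.99 to 3.93). A TCR-activated-like cluster 9 held 2.16% (1.81 to 2.56), but this share ran from 0% to 10.4% when the filters or the clustering resolution were changed, so it gives no firm size. Cluster 7, with 4.65% (4.13 to 5.21), met the marker rule for exhausted CD8 T cells but was left without a name, because Tnfrsf4, Ccr8, Areg and Maf were among its 10 leading genes. It also held transcripts of Cd4, Foxp3 and Ikzf2, at 39.2, 28.4 and 103 CPM. Over all CD8 T cells these stood at 3.16, 1.86 and 14.9 CPM. That class includes the 280 cells of cluster 7 itself, which stay in the levels below unless stated. Over all other kept cells Ikzf2 stood at 9.95 CPM. Cluster 3 held the muscle transcripts Mylpf and Acta1, at 62.6 and 48.3 CPM. Over all CD8 T cells, which include cluster 3, these stood at 11.2 and 6.19 CPM. Over all kept cells outside cluster 3, Mylpf stood at 4.65 CPM. All of these genes of clusters 3 and 7 were chosen after their values were seen. The remaining clusters of CD8 T cells had no name by the marker rule and held 59.3% (58.0 to 60.5) of the kept cells. Cluster 1 was the largest of these, with 42.9% (41.7 to 44.2) of the kept cells, but the share of the largest cluster was 50.9% at resolution 0.3 and 19.0% at 1.0, so it gives no firm size either. A B-like cluster 11 held 97 cells, 1.61% (1.31 to 1.96), and was left out, which left 5927 cells for the levels below. The genes that define these clusters by fold were, for cluster 2, Cx3cr1, Gzma and S1pr5. They were Igfbp4 and Dapl1 for cluster 3, Hspa1a and Hspa1b for cluster 4, Nrgn and Tnfrsf4 for cluster 7, and Penk and Crtam for cluster 9. Immunoglobulin and haemoglobin genes were among the leading genes of cluster 8, beside Pclaf and Birc5, and its cells had a median of 13181 UMIs.

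**Figure D4:**
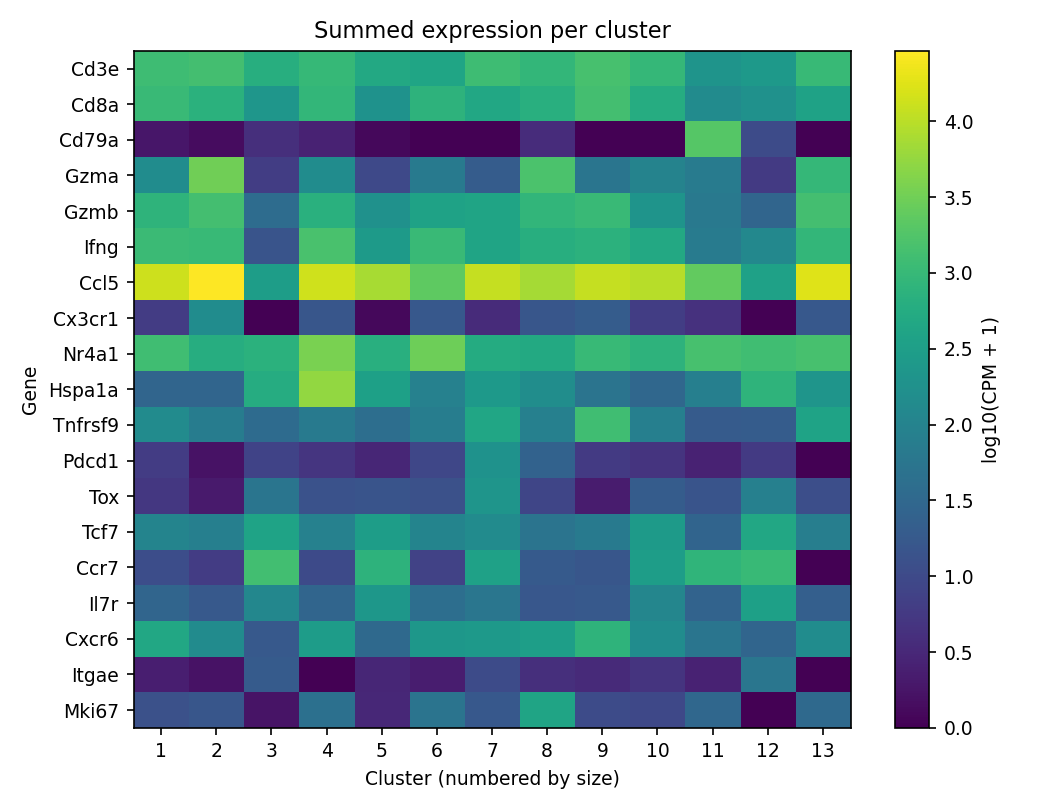
Summed expression per cluster as log10(CPM + 1) (colour scale) of 19 genes (y axis) in the 13 clusters (x axis, numbered by size). Gzma stands highest in cluster 2 at 3146 CPM, Hspa1a and Nr4a1 in cluster 4, and Cd79a in the B-like cluster 11.

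Across the CD8 T cells, effector genes were abundant and inhibitory receptor genes were mostly low. Of the 15 cytotoxic genes measured, 13 reached 50 CPM. Nkg7, a cytotoxic granule protein, stood at 1580 CPM (1567 to 1593), granzyme B (Gzmb) at 679 (671 to 688) and granzyme A (Gzma) at 593 (585 to 601), whereas Cx3cr1 and S1pr5 stood at 23.0 and 15.7 CPM. These levels pool the barcode endings, and the order of the granzymes turned, with Gzmb at 496.5 and Gzma at 224 CPM in ending 1 and at 885 and 1009 CPM in ending 2. Of 10 cytokine and chemokine genes, 5 reached 50 CPM, led by the chemokine Ccl5 at 12284 CPM, Ccl4 at 883 CPM and interferon gamma (Ifng) at 798 CPM (789 to 807). Il2 was at 3.30 CPM (2.74 to 3.93). Of 12 inhibitory receptor and exhaustion genes, 3 reached 50 CPM, namely Nr4a2 at 405 CPM, Tigit at 192 CPM and Ctla4 at 89.4 CPM, and 7 of the 12 were highest in cluster 7, where Cd4, Foxp3 and Ikzf2 were raised as well. The list includes the exhaustion markers by which cluster 7 met the marker rule, so its place there is not a separate result. Without cluster 7, an alternative added after seeing the data, Nr4a2, Tigit and Ctla4 stood at 406, 169 and 68.2 CPM. B-like cells had 70.2 CPM of Ifng, 70.2 CPM of Gzma and 35.1 CPM of Tigit. These values cannot tell free RNA from doublets with T cells, which were not effectively removed. The B-like cluster also held the monocyte or macrophage markers Lyz2 and Apoe, at 358 and 368 CPM, against 1.54 and 1.73 CPM over CD8 T cells. Ly6c2 of the same marker set was lower there, at 150.5 against 824 CPM.

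Most of the genes induced by TCR signalling were present, but B-like cells had many of them too. The median over the list was 244 CPM in CD8 T cells and 169 CPM in B-like cells. Of 17 members, 12 reached 50 CPM, with Junb at 1724 CPM, the phosphatase Dusp2 at 1097 CPM and Nr4a1, the gene that the reporter follows, at 1077 CPM (1067 to 1088). Nr4a1 stood above Dusp2 in ending 1, at 1256 and 938 CPM, and below it in ending 2, at 876 and 1276 CPM. Egr3 and Spry2 were the lowest, at 6.99 and 3.35 CPM. Nr4a1 was highest in the heat-shock-led cluster 4, at 3652 CPM, followed by the low-UMI cluster 6 at 2989 CPM, and stood at 1030 CPM in cluster 9. The dissociation stress list shares Nr4a1, Junb, Fos and Egr1 with it, and 13 of its 15 members reached 50 CPM, led by Jund at 3567 CPM and Hsp90aa1 at 1334 CPM. In B-like cells Nr4a1 stood at 1458 CPM.

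Of the 13 progenitor and memory genes, 9 reached 50 CPM, with Klf2 at 1113 CPM, Ccr7 at 269 CPM and the transcription factor Tcf7 at 157 CPM, while Bcl2 and Slamf6 were at 40.2 and 13.6 CPM. By barcode ending, 12 and 8 of the 13 reached 50 CPM, and Ccr7, at 458 CPM in ending 1 and 57.3 CPM in ending 2, stood above Tcf7, at 202 and 105 CPM, in ending 1 alone. Of 14 tissue residency genes, 6 did, with Rgs1 at 873 CPM, Cd69 at 554 CPM and the chemokine receptor Cxcr6 at 292 CPM. The integrin gene Itgae, which encodes CD103, was the lowest at 4.07 CPM (3.45 to 4.77). B-like cells had 1215 CPM of Klf2 and 843 CPM of Ccr7, above the CD8 T cells, and 26.8 CPM of Tcf7, 450 CPM of Cd69, 276 CPM of Rgs1 and 53.5 CPM of Cxcr6. All 16 cell cycle genes, which include the markers by which cluster 8 was named, were highest in cluster 8. Over all CD8 T cells 4 of them reached 50 CPM, led by Pcna at 143 CPM. Of 13 interferon response genes measured, 6 reached 50 CPM, led by Irf7 at 330 CPM, and the median over the list was 19.0 CPM in CD8 T cells and 23.4 CPM in B-like cells. Of 13 glycolysis and hypoxia genes, 11 did, led by Gapdh at 2030 CPM and Ldha at 799 CPM. Of 14 NK-type receptor genes, 2 did, Cd7 at 209 CPM and Klrc1 at 94.0 CPM, and 12 of the 14 were highest in cluster 13, which had 29 cells. The list includes Fcer1g and Tyrobp, the leading genes of cluster 13, so its place there is not a separate result.

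TCR variable gene transcripts could be assigned in 4195 of the 5927 CD8 T cells for the beta chain, 70.8%, and in 2424 for the alpha chain, 40.9%. Trbv12-1 was the most frequent beta gene with 31.3% (29.9 to 32.7) of assigned cells, followed by Trbv26 with 14.0% (13.0 to 15.1) and Trbv13-2 with 7.39% (6.62 to 8.22). This order pools the barcode endings and turned within ending 1, where Trbv12-1 had 4.94% (4.07 to 5.93), Trbv26 20.5% (18.9 to 22.3) and Trbv13-2 13.0% (11.7 to 14.5). Within ending 2 they had 59.9% (57.7 to 62.0), 6.92% (5.85 to 8.12) and 1.24% (0.807 to 1.83). Among alpha genes Trav8d-1 led with 13.6% (12.3 to 15), then Trav8-1 with 12.5% (11.2 to 13.9) and Trav13-1 with 10.4% (9.21 to 11.7). These ranks were carried by ending 2, with 24.0%, 21.8% and 15.8%, whereas ending 1 had 0.375%, 0.656% and 3.56%, and 11.8% of Trav7-4. Mouse Trav genes include near-identical copies, so the shares of single alpha genes are uncertain. The pooled order also turned when 5 UMIs were required, with Trav13-1 at 18.4% (15.9 to 21.1), Trav8-1 at 11.1% and Trav8d-1 at 9.15%. Trbv12-1 was found in 46.2% (42.2 to 50.3) of assigned cells of the effector-like cluster 2 and in 39.7% (37.5 to 41.9) of cluster 1, but in 6.90% (4.63 to 9.81) of cluster 3 and 8.26% (5.56 to 11.7) of cluster 5. This contrast pools barcode endings that the clusters hold unequally, and it was not seen within ending 1, where the shares of clusters 2, 1, 3 and 5 were 6.25% (2.90 to 11.5), 2.48% (1.5 to 3.85), 7.12% (4.71 to 10.3) and 7.23% (4.64 to 10.7). Within ending 2 they were 58.7% (54.0 to 63.2), 64.1% (61.3 to 66.8), 4.88% (0.596 to 16.5) and 23.8% (8.22 to 47.2), the last 2 from 41 and 21 assigned cells. Trbv26 was found in 31.3% (25.3 to 37.8) of cluster 4 and 36.4% (27.4 to 46.3) of cluster 9, but in 1.42% (0.293 to 4.08) of cluster 7. Within ending 1 these shares were 42.0%, 41.5% and 1.69%, and within ending 2 they were 14.6%, 0 of 13 cells and 0 of 34 cells. The splits by cluster within an ending were chosen after seeing the data. The tables of clonotypes name no V genes and no barcodes, so these cells could not be joined to clonotypes.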

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

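All tests in this part were chosen after the results were seen, except the test of sequence distances. Several signals came from data outside the comparisons. In the CD8 sort, 97 cells formed a B-like cluster, with Cd79a at 1944 CPM. A cluster of 29 cells was led by Fcer1g and Tyrobp. Of the fixed muscle markers, Mylpf, Acta1, Tnnt3 and Ckm stood at 62.6, 48.3, 46.2 and 26.1 CPM in the naive or memory-like cluster 3. Over all CD8 T cells, which include cluster 3, they stood at 11.2, 6.19, 6.22 and 3.19 CPM. These genes were chosen after their values were seen. The haemoglobin gene Hbb-bs stood at 193 CPM in the cycling-like cluster 8. The clonotype tables noted MAIT evidence for 492 Nur77-GFP+ cells and 134 TSKb20 cells, in 0 cases from the alpha chain.

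The sharing of clonotypes was lopsided: the largest Nur77-GFP+ clonotypes recurred among TSKb20 cells, and 9 of the 10 largest TSKb20 clonotypes were not seen among Nur77-GFP+ cells. Carryover into the TSKb20 library at one constant rate is argued against, since the ratio of TSKb20 to Nur77-GFP+ cells among the 10 largest Nur77-GFP+ clonotypes ran from 0.0161 (0.000402 to 0.0933) to 0.591 (0.349 to 0.981), although these are the extremes of 10. Exchange at the same rate both ways would have put 256.2 cells of those 9 clonotypes into the Nur77-GFP+ library, where 0 were seen. A Nur77-GFP+ gate that left out tetramer-binding cells stays open: 0.125% of paired Nur77-GFP+ clonotypes carried both TSKb20 motifs described next, against 14.2% in TSKb20, and low signalling in such cells would give the same. The 2 sorted populations themselves remain an untested biological explanation, and carryover of part of the cells is not excluded. Each library was a pool of 5 mice whose cells cannot be told apart. Unequal contributions of single mice to the 2 pools are therefore not excluded either.

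In the TSKb20 library, 31 of 218 paired clonotypes, with 1230 cells, combined DWG in the beta CDR3 with AGAKLTF at the end of the alpha CDR3. Errors in the beta sequence that split a few clones are argued against, because 0% of the 31 had a larger neighbour with the same alpha sequence and a beta sequence at most 2 bases away. The 31 held 34 different alpha and 33 different beta nucleotide sequences. Splits by errors in the alpha sequence had no test of their own, since only neighbours of the same alpha sequence were counted. Whatever the alpha sequence, the nearest beta sequence of another of the 31 was a median of 3 bases away. An alpha error alone would leave the beta sequence unchanged, but clonotypes with an identical beta sequence were not counted. DWG, picked for its excess in TSKb20, was found in 20.8% of TSKb20 and 7.11% of Nur77-GFP+ beta sequences, and GACTGGGGG coded it in 71.2% and 80% of these. The alpha ending was found in 63.3% (48.3 to 76.6) of TSKb20 clonotypes with DWG and in 9.47% (5.51 to 14.9) of those without, which argues against germline D segments as the whole cause, since these leave the alpha chain free, and is consistent with selection of both features together. This is a hypothesis found and tested on the same library, whose motifs were picked from 137 beta and 33 alpha motifs.

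Nr4a1 was highest in the heat-shock-led cluster and high in B-like cells. Free RNA from CD8 T cells is argued against as the source in B-like cells, where Nr4a1 was 1.35 times (1.26 to 1.45) its level in CD8 T cells while no CD8 T marker exceeded 0.268 times. Dissociation stress without TCR signalling cannot be told apart from signalling in the heat-shock-led cluster. Of 13 TCR-induced genes outside the stress list, 9 genes, 69.2%, were above the other CD8 T cells. Among these were Nfkbid at 3.46 times, Egr3 at 2.05 times and Nr4a2 at 1.81 times. Below them were 2, Tnfrsf9 at 0.486 times and Tnfrsf4 at 0.188 times, and the other 2 were neither. No biological explanation was tested here, because the design gives no group for these cells.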

How the results depend on the processing

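No paired analysis was possible because each group was 1 library. Doublet alternatives, merged clonotypes and the settings without cluster 7 or 13 were chosen after seeing the data. Of 313 values of the main results other than list medians under an alternative, 237 stayed within their interval or 1.5 times their count and 76 moved. Of 88 list medians by barcode ending, 17 changed sign and 8 entered or left the middle 95% of random lists: cell cycle changed sign in 3, interferon in 4, glycolysis in 2 and NK-type receptors in all 8 alternatives. In every expansion alternative the 10 largest clonotypes held more of the TSKb20 than of the Nur77-GFP+ cells. In Nur77-GFP+ they held 31.6% by beta amino acids alone, 32.9% with at least 1 alpha and 1 beta, 35.3% with exactly 1 of each (698 clonotypes) and 22.5% without the largest; in TSKb20 64.9%, 68.1% and 57.1% under the last 3. The largest clonotype held 9.79%, 11.4% and 3.31% of Nur77-GFP+ cells under the last 3 and 19.0% of TSKb20 cells with exactly 1 of each chain. With at least 1 alpha and 1 beta and with exactly 1 of each, 36 and 29 clonotypes held 50% of Nur77-GFP+ cells and the effective numbers were 242.8 and 202.3. Clonotypes of 1 cell held 38.0% of Nur77-GFP+ cells after merging, 37.6% by amino-acid sequences of all chains, 35.8% by beta amino acids alone, 31.8% and 32.7% with the chains required and 43.95% without the largest. In TSKb20 the last 4 were 6.15%, 5.74%, 5.48% and 9.66%. Shared clonotypes numbered 88 (44.1% of Nur77-GFP+ cells) by any beta nucleotide sequence, 96 (44.9%) by any beta amino-acid sequence and 30 (33.4%) with at least 2 cells in each library; without the most frequent one they held 36.0% of Nur77-GFP+ and 7.95% of TSKb20 cells. Paired chains were found in 71.5% of Nur77-GFP+ and 77.7% of TSKb20 clonotypes. Among clonotypes of at least 2 cells, 15-residue beta CDR3 made up 16.9% in Nur77-GFP+ and 43.6% in TSKb20, and sequences in groups 10.6% and 28.4%. Weighted by cells, groups held 23.1% and 62.5%, and 15 residues 66.2% in TSKb20.

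The TCR-activated-like share was 0% at resolution 0.3, 3.32% at 1.0, 9.04% with Scrublet calls kept, 8.76% without the highest Scrublet scores, 2.62% without cells of 2 Trbv genes, 10.4% at 5% mitochondrial UMIs, 3.01% at 20% and 2.67% with 200 genes. The largest cluster held 50.9% at resolution 0.3, 19.0% at 1.0, 39.4% with Scrublet calls kept, 39.5% without the highest scores, 39.35% without cells of 2 Trbv genes, 44.2% at 5% mitochondrial UMIs and 36.4% at 20%. Clusters with no name by the marker rule held 61.3%, 52.1%, 52.4%, 51.6%, 47.0%, 49.4% and 46.7% in the same order, and 53.4% with 200 genes. At resolution 1.0, at 20%, with 200 genes and without cells of 2 Trbv genes, cells named as muscle or erythroid lie outside these shares. The cycling-like share was 2.27% at resolution 1.0, the naive or memory-like share 16.2% without the highest Scrublet scores, and the share of clusters with exhaustion markers 4.04% without cells of 2 Trbv genes. Trbv12-1 fell to 29.3% and Trav8d-1 to 9.15% at 5 UMIs, where Trav13-1 led with 18.4%, and Trbv19 with 7.22% passed Trbv13-2 with 6.60%. The cause was not tested. The number of genes higher in barcodes ending in 1 or 2 was 51 and 101 of 2966. It became 111 and 51 of 3705 without TCR, immunoglobulin, mitochondrial and ribosomal protein genes in the total and 90 and 43 of 2919 with TMM factors. Over the same 2966 genes these scalings gave 86 and 42, and 86 and 44, so the turn came with the scaling. After 1 random thinning, which also left out cells, the numbers were 35 and 28 of 3017. Means over cells gave no such count. Of the list medians of the log2 ratio of ending 1 over 2, cell cycle was -0.0057 as means over cells, -0.0058 after thinning and -0.17 without the cycling cluster, glycolysis 0.0016, inside the middle 95%, as means over cells, -0.0055 without the cycling cluster and -0.0027 at 5% mitochondrial UMIs, and interferon, above the middle 95%, 0.18 as means over cells and 0.12 after thinning. Pdcd1, at 2.21 times in ending 1 relative to ending 2, was at 0.819 times (0.620 to 1.08) without cluster 7, whereas Cd4, at 2.31 times, was at 2.45 times (1.23 to 5.25). Mki67, at 1.11 times in ending 1 relative to ending 2, was at 0.899 times (0.739 to 1.09) without the cycling cluster. Of 808 values of single genes, 508 stayed within their counting interval, 298 moved and 2 reversed. Of the moved values, 92 came under the total without TCR, immunoglobulin, mitochondrial and ribosomal protein genes. That total rescales all genes of a set of cells by a common factor. TMM factors, which also rescale all genes of a set together, moved 25. The causes of the other moves were not tested either. With 1 library each, depth narrows counting error but not differences between mice.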

Other observations

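Values per barcode ending are given for unassigned sets of cells, without direction between the sorted populations. Among CD8 T cells, 2961 barcodes ended in 1 and 2966 in 2. The endings held clusters unequally: clusters 3 and 5 had 452 and 371 cells in ending 1 but 52 and 24 in ending 2, cluster 2 had 178 and 661, and cluster 7 had 228 and 52. Ccr7 stood at 458 CPM in ending 1 and 57.3 CPM in ending 2, Xcl1 at 116 and 26.9 CPM, and Il7r at 84.1 and 37.9 CPM. Gzma stood at 224 and 1009 CPM, Klrg1 at 92.1 and 197.5 CPM, Gzmb at 496.5 and 885 CPM, Ifng at 663 and 951 CPM, and Nr4a1 at 1256 and 876 CPM. The ratio for Ccr7 was 7.99 (7.49 to 8.54) and for Gzma 0.222 (0.215 to 0.229). The median log2 ratio of ending 1 over 2 was 0.93 for the progenitor and memory list, at percentile 100 of 10000 matched random lists, and -0.54 for the cytotoxic list, at percentile 0. It was 0.40 for the dissociation stress list, 0.26 for the TCR-induced list and 0.28 for the inhibitory receptor list, each at percentile 100, and -0.53 for the cytokine list, at percentile 0.01. The cytokine list was at percentile 2.27 as means over cells and 2.01 after thinning. Its median level ran the other way, at 82.6 CPM in ending 1 and 34.7 CPM in ending 2, although 2 of its 10 members were higher in ending 1. The random lists were drawn gene by gene from the same cells, so the percentiles measure no variation between mice. Genes of a list that vary together can reach the extremes more easily. Without cluster 7, an alternative chosen after seeing the data, the inhibitory receptor list stood at 0.06 (percentile 98.2), and Pdcd1, at 2.21 times (1.84 to 2.67) in ending 1 relative to ending 2, stood at 0.819 times (0.620 to 1.08). Cd4 stood at 2.31 times (1.53 to 3.57) over all CD8 T cells and at 2.45 times (1.23 to 5.25) without cluster 7. The cell cycle list (0.02, percentile 99.4) and the glycolysis list (0.01, percentile 97.8) lay just above the middle 95% of random lists, but both changed sign under other settings. The residency (-0.31), interferon (-0.07) and NK-type receptor (-0.01) lists lay inside it, and no direction is given for the last 2. The interferon median was positive in 4 of 8 alternatives (with TMM factors, with the reduced total, as means over cells and after thinning), and the NK-type median in all 8. The median over the 2966 genes considered was itself -0.20 in summed counts, and over the same genes it was -0.05 with TMM factors or without TCR, immunoglobulin, mitochondrial and ribosomal protein genes in the total. The number of genes past the ratio of 1.5 was 51 towards ending 1 and 101 towards ending 2 in summed counts, 90 and 43 with TMM factors, and 111 and 51 without those genes in the total. Over the same 2966 genes the last 2 settings gave 86 and 44, and 86 and 42.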
